A study of Bos taurus with 8 samples.

How the data were processed

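Bovine embryos were produced in vitro and cultured to the blastocyst stage with or without AAPH, a compound that decomposes to peroxyl radicals. RNA of pools of 10 blastocysts was amplified and labelled with Cy3 or Cy5, and 8 two-colour arrays each carried AAPH RNA in 1 dye and control RNA in the other. The deposited scanner files hold the foreground and local background intensity of each spot in both dyes on a linear scale, per the file headers, and the scanner software is not given in the sources used here. Each file also held 14 lines of column statistics that were not spots and were left out. A deposited table of log2 ratios made by the authors covers the same arrays, and limma is named in the submitters' processing notes without a version or settings. Set against the scanner ratios over bright probes, its columns had slopes of 0.948 to 1.01 and correlations over all probes of 0.967 to 0.994, so its scale was log2 and its direction AAPH over control on all 8 arrays. Its column medians, from array 1 to array 8, were -0.0135, -0.00863, 0.0117, 0.00944, -0.0152, 0.00799, -0.0188 and -0.0197. Its normalization method remains unknown, and it served as an alternative.

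Intensities were read in R 4.3.3 and processed with limma 3.58.1. Mean foreground and median background were corrected with normexp and an offset of 50, each array was normalized with loess in which control spots had a weight of 0, and ratios of the arrays with AAPH in Cy3 were turned so that all were AAPH over control. No scaling between arrays was applied for the tests. Signal per pool, given where levels are named, came from the same values after Aquantile scaling, and such levels can be compared between pools for 1 gene but not between genes. A probe counted as above background on an array when its signal exceeded the median of the negative control spots by 3 median absolute deviations, and was kept when this held on at least 4 of the 8 arrays in AAPH RNA or in control RNA. This left 31325 of 43794 probes. The threshold on the negative controls was set after the control spots had been seen, since a few bright outliers among them had inflated a rule based on the mean and SD.

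Gene symbols came from the platform's annotation, which is old: 21790 probes had 1 symbol, 0 had several and 22004 had none in the table used here. Of 15229 distinct symbols, 14114 matched a symbol and 1019 a synonym in the RefSeq gene table of assembly ARS-UCD2.0, and 96 matched neither. Symbols are given as in the annotation. The build of the probe design is not given in the sources used here, so no coordinates are reported.

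The design text gives 4 pools per treatment and 4 arrays in each dye orientation, without saying which arrays share their extracts. A rule fixed before the data were examined paired arrays of opposite orientation by the correlation of their deviations from the orientation mean. The best of the 24 pairings had correlations of 0.155 to 0.569, all above the required 0.1, and each array correlated best with its partner. The 12 other pairs had correlations of -0.343 to 0.0438. Arrays 1 and 3, 2 and 4, 7 and 5, and 8 and 6 were therefore averaged as swap pairs 1 to 4, which removes a constant dye effect and leaves n = 4 with 3 residual degrees of freedom. This pairing was derived from the data and is not stated in the labels. Nothing in the labels says that the pools came from separate fertilization runs, so p-values measure the spread between these pools.

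The ratio of AAPH over control was tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 36 gene lists fixed before the data were examined, 34 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, using the brightest kept probe of each of 12203 genes. The named genes followed a rule fixed at the same time: up to 12 probes in each direction with an adjusted p under 0.05 and the same sign in every swap pair, filled with those of smallest p where fewer passed; up to 4 members of smallest p in each list; and a set of antioxidant and lineage genes. Genes outside this rule are marked as chosen after their values were seen. A gene list's count "adjusted over the list alone" uses Benjamini-Hochberg over its own members.

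The procedure was tested on 5 simulated data sets of 31325 probes for the comparison of AAPH with control, with 200 changed probes in each. The true swap pairs were recovered in all 5, 5.36% of unchanged probes had an unadjusted p under 0.05, and 19.7%, 85.1% and 98.5% of probes changed by 0.5, 1 and 2 on the log2 scale were called. Averaged swap pairs gave a mean of 140.8 calls with 5.6 false ones, and 8 single arrays gave 285.4 calls with 107.2 false ones. The simulated variances came from the pairing used here, and the noise was independent between probes. Recovery of the pairs and the false calls of single arrays were therefore partly built in. Probes that vary together were not simulated, so 5.36% need not hold for the real arrays. Changed probes were drawn at random, so the shares called need not hold for probes that vary more between pools. On the real arrays 53 probes were higher and 5 lower with a fold of at least 2 and the same sign in every swap pair. Of these, 0 were called.

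Alternatives changed the background correction, the normalization within and between arrays, the filter on dim probes, the unit of replication, the pairing, the treatment of dye and slide, the threshold, the set test and the probe of a gene, left out each swap pair in turn, and used the authors' log2 values. Trimmed-mean foreground, a filter at 2 times the negative controls, regression on the dye effect and all alternatives for the Y-linked genes were added after seeing the data. The number of arrays limits the precision. The 90th percentile of probe signal was 7.51 to 14.2 times the negative controls in AAPH RNA and 9.06 to 15.4 times in control RNA.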

Results

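Gene expression was measured in pools of 10 bovine blastocysts collected 196 hours after in vitro fertilization. Embryos were cultured with 0.01 mM AAPH, a generator of peroxyl radicals, from day 3 to day 7, or without it. Each treatment had 4 pools, compared on 8 two-colour arrays, of which 4 carried AAPH RNA in Cy5 and 4 in Cy3. Between 15525 and 36330 probes were above background per array in AAPH RNA and between 13803 and 36079 in control RNA. The comparison asks which transcripts differ in blastocysts exposed to a radical generator. All ratios are AAPH over control on the log2 scale, with the SD over 4 swap pairs.

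The list of fibroblast and connective tissue markers rose as a group in AAPH blastocysts with camera at the preset correlation, but not in every set test. LUM, which encodes the matrix proteoglycan lumican, had a log2 ratio of 2.86 ± 1.52 (SD, n = 4), and VIM, the mesenchymal intermediate filament vimentin, had 1.86 ± 0.62. COL3A1, a fibrillar collagen, was at 1.61 ± 0.76, and all 3 genes were higher in AAPH in 4 of 4 swap pairs. COL3A1 was above background on 5 of 8 arrays in control RNA and on 8 of 8 in AAPH RNA. Of the 10 measured members 9 had a positive ratio, with a median of 0.71 (camera, adjusted p = 1.81e-05). This call was lost with an estimated correlation between genes (adjusted p = 0.803) and with fry, which asks whether a list moves 1 way without comparing it with other genes (adjusted p = 0.213). No member passed after adjustment over all probes, and 5 passed when adjusted over the list alone: LUM, VIM, COL3A1, POSTN and COL1A1. COL1A1 was close to background, at 0.31 ± 0.23, and COL1A2, chosen like POSTN after its values were seen, was at 0.67 ± 0.78, with a negative ratio in swap pair 4. The list median was 1.17 within slide 26 (adjusted p = 2.23e-07) and 0.255 within slides 78 and 79 (adjusted p = 0.0217), and the difference between slides was not tested. Slide 26 held only swap pairs 1 and 2, and slides 78 and 79 only pairs 3 and 4. These camera p-values reflect the number of genes at the preset correlation and say little about the spread between pools. Without swap pair 1 the list median was 0.417 (adjusted p = 0.000719), and it was 1.61 over the 5 members above background on all 8 arrays of a treatment (adjusted p = 1.43e-06). Of these, VIM, COL3A1 and POSTN entered only through AAPH RNA, with 7, 5 and 7 arrays above background in control RNA. The filter thus favoured members high in AAPH, and that larger median adds no support.

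**Figure D1:**
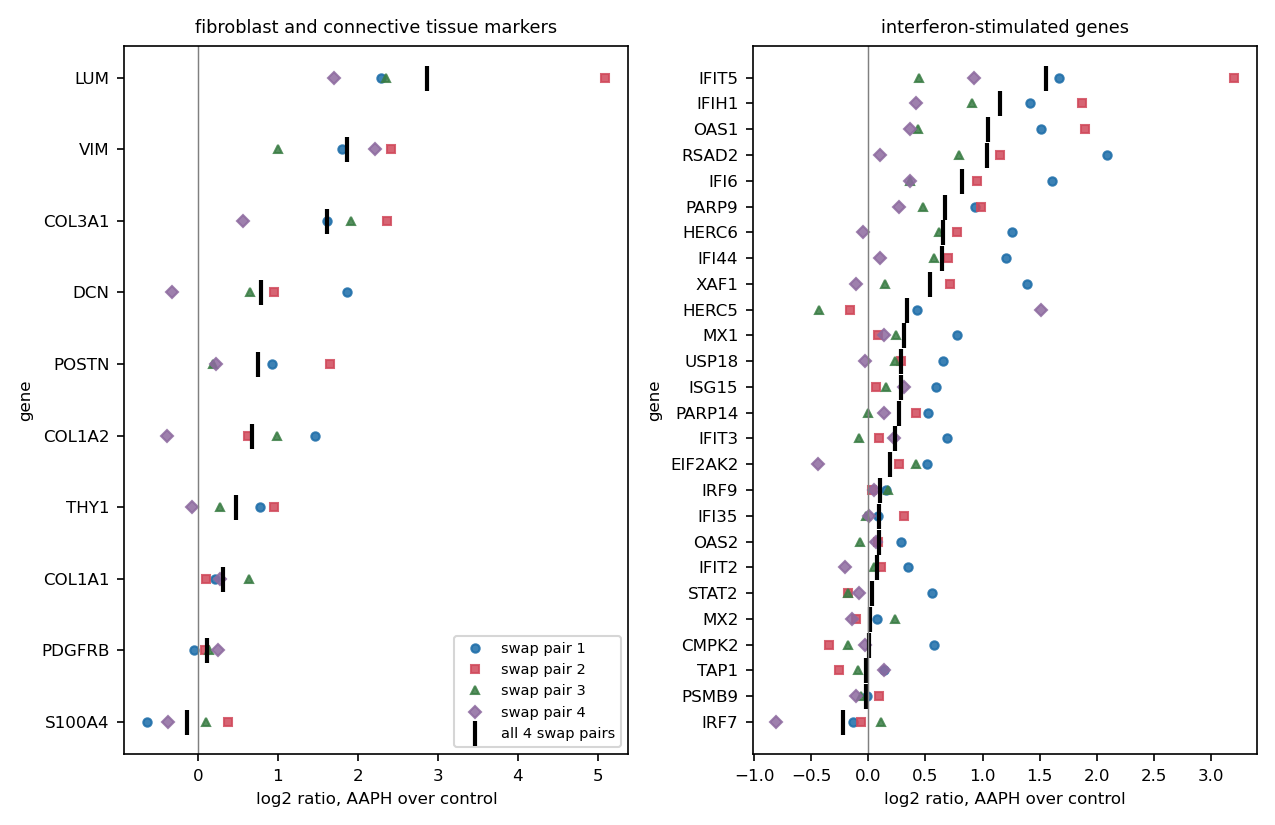
Log2 ratio of AAPH over control (x axis) for each measured member of 2 gene lists (y axis), with 1 symbol per swap pair and a bar at the mean of 4. LUM, VIM and COL3A1 lie above 0 in 4 of 4 swap pairs, with means of 2.86, 1.86 and 1.61.

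Interferon-stimulated genes also rose as a group in AAPH blastocysts with camera at the preset correlation, but not in every test or filter. IFIH1, a sensor of double-stranded RNA, had a log2 ratio of 1.15 ± 0.63 (SD, n = 4), OAS1, an activator of RNA decay, had 1.05 ± 0.77, and PARP9 and IFI44 had 0.67 ± 0.35 and 0.64 ± 0.45. IFI44 was above background on 7 arrays in AAPH RNA and on 5 in control RNA. In swap pair 4 IFIH1 was above background on 1 of 2 arrays in both treatments. Of 26 measured members 23 had a positive ratio, with a median of 0.28 (camera, adjusted p = 1.81e-05), and the call was lost with an estimated correlation (adjusted p = 0.803), with fry (adjusted p = 0.487) and when signal above background was required on all 8 arrays of a treatment, which left 7 members with a median of 0.336 (adjusted p = 0.125). With a filter at 2 times the negative controls, chosen after seeing the data, the 9 members left had a median of 0.667 and passed (adjusted p = 0.00123). As for the fibroblast list, such a filter can favour members high in AAPH, so the larger median adds no support. RSAD2, HERC6 and IFI6, chosen after their values were seen, met the main filter only in AAPH RNA. They were above background on 3, 3 and 2 arrays in control RNA. No member passed over all probes, while 8 passed when adjusted over the list alone. IFIT5, chosen after its values were seen, was at 1.56 ± 1.21, and at 1.01 without swap pair 2. The trophoblast interferon transcript IFNT was at 0.05 ± 0.51, positive in 3 of 4 swap pairs, and its sign changed between alternatives. The list median was 0.391 within slide 26 (adjusted p = 3.47e-10) and 0.0848 within slides 78 and 79, where the list did not pass (adjusted p = 0.245). The former rests on swap pairs 1 and 2 alone and the latter on pairs 3 and 4, so these p-values say little about the spread between pools. Without swap pair 1 the list median was 0.158 (adjusted p = 0.0327). Beside both lists, markers of cumulus and granulosa cells had a median of 0.05 and did not pass, although their members PTX3 and TNFAIP6 were at 1.10 ± 0.91 and 0.85 ± 0.95, and at 0.73 and 0.50 without swap pair 1.

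No single probe passed the test. With limma, 0 of 31325 probes had an adjusted p under 0.05 and the smallest adjusted p was 0.144, while 4277 probes had an unadjusted p under 0.05 against 1566 expected by chance, 1794 of them higher and 2483 lower in AAPH. limma with a variance trend and robust variances also gave 0 probes, with 2561 at an unadjusted p under 0.05. That trend was fitted on the mean log2 ratio of each probe, so a trend with intensity was not tested. The same sign in 4 of 4 swap pairs was seen for 22.3% of probes, and chance gives 12.5%. Requiring signal above background on all 8 arrays of a treatment, an alternative fixed in advance, left 14358 probes, of which 29 passed (14 higher and 15 lower, all at an adjusted p of 0.0459). LUM, VIM, COL3A1, RNF128, MLLT11 and LIX1L were among those higher, and HAX1, DHODH, ARRB2 and LOC613677 among those lower. VIM and COL3A1 met the filter only in AAPH RNA, and LOC613677 only in control RNA.

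The 12 genes of smallest p that were higher in every swap pair had folds of 1.42 to 3.63 and did not pass over all probes. They were RNF128, ZNF385B, LIX1L, MLLT11, RESP18, VIM, L1CAM, DAZAP2, FGG, TWSG1, PHTF1 and HECA. RNF128, a ubiquitin ligase, was at 0.80 ± 0.17 (SD, n = 4), and the cell adhesion molecule L1CAM was at 0.56 ± 0.10. ZNF385B was at 1.32 ± 0.39 and above background on 6 arrays in AAPH RNA and on 4 in control RNA. In swap pair 4 it was above background on 0 of 2 arrays in both treatments and in swap pair 2 on 0 of 2 in control RNA, so its sign in the former was not measured. The 12 lower genes had folds of 1.47 to 2.02 and did not pass either. They were LOC613677, HAX1, IGJ, DHODH, GGTA1, TMEM103, IL1RN, ZNF583, LOC616478, ARRB2, GDPD5 and WIPF1. DHODH, a mitochondrial enzyme of pyrimidine synthesis, was at -0.93 ± 0.21, HAX1, a mitochondrial protein that limits apoptosis, at -0.80 ± 0.13, and ARRB2, an arrestin, at -1.02 ± 0.34. AAPH signal of the 12 lower genes ran in 1 order over the pools, highest in swap pair 1, then 2, 4 and 3. For HAX1 it was 10.59, 9.921, 7.989 and 8.814 in pairs 1 to 4, and for DHODH 10.08, 9.465, 7.753 and 8.779. Control signal ran in the same order for all of these genes except WIPF1. For HAX1 it was 11.23, 10.67, 8.84 and 9.752, and for DHODH 10.75, 10.33, 8.919 and 9.793. The order was thus not particular to AAPH RNA, and both pools of a swap pair share their arrays. These genes may therefore not be separate findings, and a shared source was not tested. TMEM103 was above background on 4 arrays in AAPH RNA, and IGJ, GGTA1 and LOC616478 on 5, with 0 of 2 in swap pair 3 for these 4 genes, so their folds depend on signal at the floor. Of the 24 genes, 11 had another kept probe. The median of the other probes had the same sign for 6 of these, and for 0 was it at least 50% as large. Of the 136 list members named by the rule, 45 had another kept probe, whose median had the same sign for 34 and was at least 50% as large for 13.

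Genes of the oxidative stress response did not move as groups. The median log2 ratio was 0.03 over 25 antioxidant enzymes, -0.03 over 25 NRF2 targets, -0.04 over 23 genes of glutathione metabolism and -0.01 over 6 metallothioneins, and none of these lists passed. HMOX1, which degrades heme, was at -0.11 ± 0.66 (SD, n = 4), and the quinone reductase NQO1 was at -0.06 ± 0.30. Superoxide dismutases SOD1 and SOD2 were at 0.37 ± 0.73 and 0.02 ± 0.27, catalase (CAT) at 0.00 ± 0.18, GPX1 at 0.03 ± 0.28 and TXNIP, an inhibitor of thioredoxin, at 0.29 ± 0.37. The signs of HMOX1, NQO1, SOD1, SOD2, CAT and GPX1 changed between alternatives. Members that passed when adjusted over the list alone went both ways. GPX8, a peroxidase of the endoplasmic reticulum, was at 1.11 ± 0.55 and PRDX4 at 0.37 ± 0.17, while TXNRD2 was at -0.30 ± 0.14, GPX3 at -0.27 ± 0.06, GSTM1 at -0.36 ± 0.09 and the metallothioneins MT1A and MT1E at -0.57 ± 0.31 and -0.31 ± 0.17. GPX3 was above background on 4 arrays in AAPH RNA and MT1E on 5. Of these genes, TXNRD2, GSTM1 and MT1E had other kept probes, with medians of -0.12, -0.05 and -0.05.

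Other stress lists did not pass. Medians were 0.01 for 20 p53 targets, -0.05 for 23 genes of the integrated stress response, 0.04 for 19 endoplasmic reticulum chaperones, -0.03 for 23 heat shock proteins, -0.02 for 24 inflammatory genes, 0.06 for 28 DNA repair genes and 0.03 for 21 autophagy genes. Of these, WARS of the integrated stress response passed when adjusted over its list alone, at -0.33 ± 0.02 (SD, n = 4). The 2 other kept WARS probes had a median of 0.03 and a range of -0.06 to 0.11. Apoptosis regulators had a median of 0.08 over 21 genes, with BCL2L2 at 0.43 ± 0.24 and CASP8 at 0.39 ± 0.26, and did not pass with camera (adjusted p = 0.242). They passed with fry (adjusted p = 0.0351). Hypoxia response genes had a median of 0.02 over 18 genes and did not pass, but HIF1A at 0.45 ± 0.10, P4HA1 at 0.33 ± 0.10, MXI1 at 0.34 ± 0.15 and PLOD2 at 1.34 ± 1.07 passed when adjusted over the list alone. P4HA1 and PLOD2 encode collagen-modifying enzymes, and PLOD2 was at 0.86 without swap pair 2. Other kept probes had medians of 0.07 for HIF1A, 0.10 for P4HA1, 0.11 for MXI1 and 0.42 for PLOD2.

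**Figure D2:**
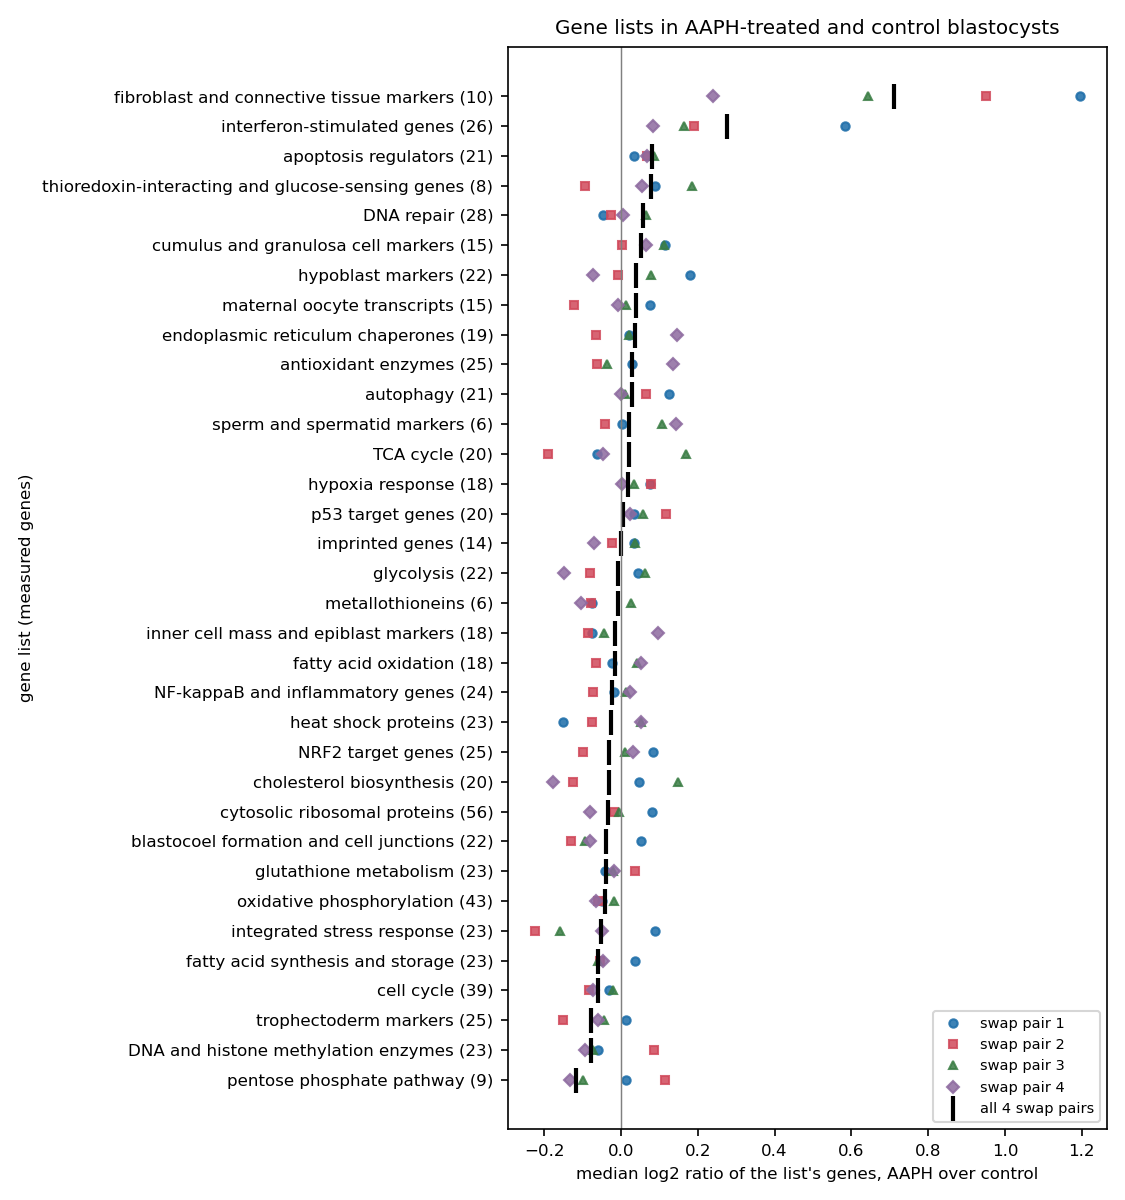
Median log2 ratio of AAPH over control (x axis) for the 34 tested gene lists (y axis, with measured genes), with 1 symbol per swap pair and a bar for the median of gene means over all 4. The fibroblast and interferon-stimulated lists, at 0.71 and 0.28, are the 2 that passed camera with the preset correlation.

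Markers of the blastocyst lineages did not pass as lists in the main fit. With loess, trophectoderm markers passed as lower in AAPH without the filter on dim probes, without swap pair 1 and with the dye effect regressed out. They also passed as lower when all kept probes of a gene were averaged. With median centring within arrays, trophectoderm markers (adjusted p = 0.00675), genes of blastocoel formation and cell junctions (adjusted p = 0.0155) and DNA and histone methylation enzymes (adjusted p = 0.0284) passed as lower in AAPH. Trophectoderm markers had a median of -0.08, with 21 of 25 genes lower in AAPH (camera, adjusted p = 0.0938). DLX3 was at -0.31 ± 0.24 (SD, n = 4), CDX2, above background on 4 arrays in AAPH RNA, at -0.11 ± 0.10 and GATA3 at -0.11 ± 0.19. Inner cell mass and epiblast markers had a median of -0.02 over 18 genes, with POU5F1 at -0.18 ± 0.28, NANOG at 0.20 ± 1.27, SOX2 at -0.02 ± 0.09 and the DNA methyltransferase DNMT3B at -0.42 ± 0.30. The signs of NANOG, SOX2 and GATA3 changed between alternatives, and GATA6 had no kept probe under its name. Hypoblast markers had a median of 0.04 over 22 genes, and APOA1 at 0.40 ± 0.13 and NID2 at 0.47 ± 0.26 passed when adjusted over the list alone. Genes of blastocoel formation and cell junctions had a median of -0.04 over 22 genes, with CLDN23 at -0.43 ± 0.22 and the water channel AQP3 at -0.30 ± 0.25. DNA and histone methylation enzymes had a median of -0.08 over 23 genes, with the demethylase KDM1A at -0.42 ± 0.21. Medians were 0.04 for 15 maternal oocyte transcripts, 0.02 for 6 sperm markers and 0.00 for 14 imprinted genes. IGF2, an imprinted growth factor, was at 2.00 ± 1.75 and negative in swap pair 4, where it was above background on 0 of 2 arrays in both treatments, and its other kept probe was at 0.10.

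Metabolic and housekeeping lists did not pass with loess. With median centring within arrays, cytosolic ribosomal proteins (median -0.15, adjusted p = 1.68e-05), oxidative phosphorylation (-0.16, adjusted p = 0.00213) and cell cycle genes (-0.12, adjusted p = 0.0174) passed as lower in AAPH. With loess, medians were -0.01 for 22 glycolysis genes, 0.02 for 20 genes of the TCA cycle, -0.04 for 43 genes of oxidative phosphorylation, -0.12 for 9 genes of the pentose phosphate pathway, -0.03 for 20 genes of cholesterol synthesis and -0.02 for 18 genes of fatty acid oxidation. Thioredoxin-interacting and glucose-sensing genes had a median of 0.08 over 8 genes, cell cycle genes -0.06 over 39 and cytosolic ribosomal proteins -0.03 over 56. Fatty acid synthesis and storage had a median of -0.06 over 23 genes, and SCD5, a desaturase, at 0.57 ± 0.15 (SD, n = 4) and ELOVL5, an elongase, at 0.53 ± 0.21 passed when adjusted over the list alone. The 2 other kept ELOVL5 probes had a median of 0.08. The mean and the median differed in sign for the TCA cycle, fatty acid synthesis and sperm lists. SDHA, a subunit of succinate dehydrogenase, was at -0.31 ± 0.13.

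Pools of 10 embryos can differ in sex ratio. The 4 measured Y-linked genes had a mean log2 ratio of -0.01 ± 0.10 (SD, n = 4; exact sign-flip test, two-sided, p = 0.875), in a design whose smallest possible p is 0.125. These probes lay near the floor, where ratios are pulled towards 0: ZFY was above background on 3 arrays in AAPH RNA and 5 in control RNA, SRY on 4 and 5, EIF1AY on 5 and 7, and DDX3Y on 6 and 6. A difference in sex ratio could therefore have been missed. XIST, the X-inactivation transcript, was at 0.31 ± 1.07 and ranged from -0.86 to 1.58 over the swap pairs. Connective tissue genes varied between pools of 1 treatment as well: LUM signal spanned 7.76 to 11.2 in control pools and 9.53 to 13.5 in AAPH pools on the log2 scale.

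**Figure D3:**
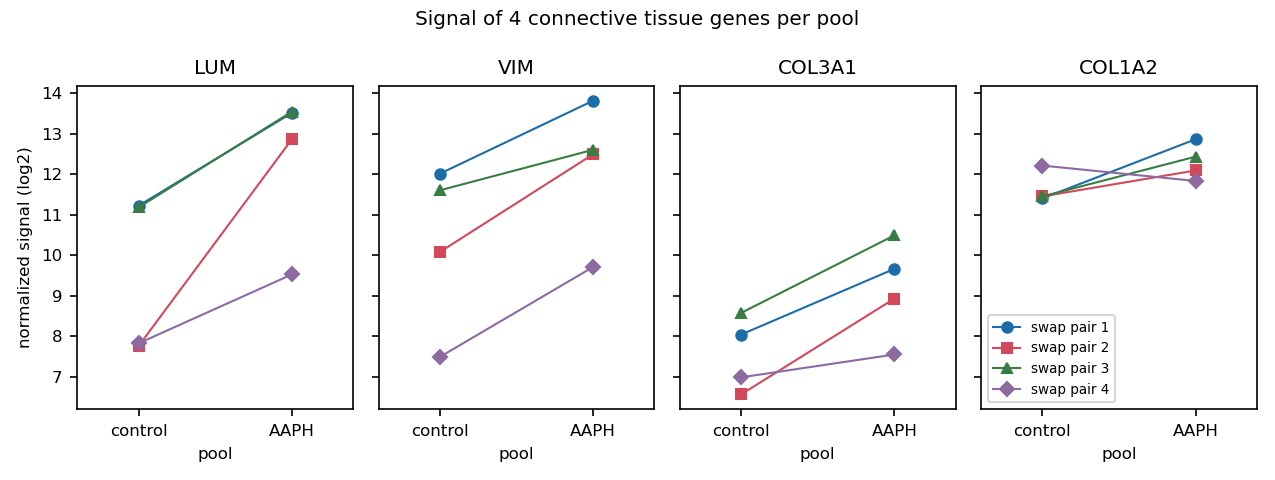
Normalized log2 signal (y axis) of LUM, VIM, COL3A1 and COL1A2 in control and AAPH pools (x axis), with 1 line per swap pair; levels are comparable within a gene only. LUM signal is higher in AAPH on each line, from control values of 7.76 to 11.2, and COL1A2 is lower in AAPH in swap pair 4.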

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

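Of the tests in this part, those on fibroblast-like cells, 1 swap pair, interferon tau and a shared programme were chosen after the result was seen. Those on dye, dim probes and sign turns were chosen after the data and the excess of probes had been seen, but before their own values.

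A swap pair far from the other 3 was found for 7 of 227 results, fewer than the 11.4 that chance gives. Swap pair 2 stood apart for TP53I3 (-0.038), SLC25A20 (-0.69), HIF1A (0.30) and OLR1 (4.69, with OLR1 above background on 1 of 2 arrays in control RNA there). Swap pair 1 stood apart for AHSA1 (-0.82), ATP5G1 (-0.038) and the median of the fatty acid synthesis and storage list (0.037).

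The median of the fibroblast and connective tissue list was above 0 in each swap pair (1.2, 0.95, 0.64 and 0.24 in pairs 1 to 4). Without swap pair 1, the highest, it was 0.417, which is 2.03 times the SE of the 3 remaining pair medians. This is only just beyond the limit of 2 set for this test. With 3 pairs such a limit cannot exclude that 1 swap pair carried much of the rise. Fibroblast-like cells in the AAPH pools may account for the rise, as may a mesenchymal programme in the embryos themselves, which was not tested. COL1A2, an abundant fibroblast transcript, had a log2 ratio of 0.67 against 1.96 for the median of LUM, COL3A1 and VIM, but its range of 2 SE reached 1.45, above the limit of 0.978 below which such cells would be argued against. COL1A2 was at 0.41 without swap pair 1 and at 1.025 without swap pair 4. The range of 2 SE of COL1A1 reached 0.539, below the limit. Its probe was near the floor, above background on 6 of 8 arrays, so it cannot count against such cells. The 2 sources cannot be told apart here for these genes.

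For the interferon-stimulated list, more interferon tau could not be told from none: IFNT had a log2 ratio of 0.052, and the range of 2 SE reached 0.56, above the list's own median. A programme or cell population shared with the fibroblast list is a candidate explanation, since the 2 lists' levels moved together over 8 pools within treatments (Pearson r = 0.932, exact permutation p = 0.0104; Spearman rho = 1.00, exact permutation p = 0.00347; r = 0.831 without the 2 pools farthest from the median). This evidence is weak, because the interferon list also followed many unrelated lists, with a median r of 0.611 over 32 others, 0.823 for trophectoderm markers and 0.901 for the highest. Pool-wide differences in signal could therefore give much of it, both pools of a swap pair share their arrays so that these p-values are too small, and each slide set held too few pools for its own correlation.

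The excess of probes at an unadjusted p under 0.05 was not explained by a dye effect common to the swap pairs. After that effect was regressed out, 13.1% of probes remained. In swap pairs 3 and 4, however, AAPH was in Cy5 on slide 79 and in Cy3 on slide 78. A dye effect particular to 1 slide would not cancel there, and this was not tested. Dim probes did not explain the excess, since the share was 22.0% among the 10442 brightest probes and 4.06% among the 10442 dimmest. Of the 8 sign turns of the swap pairs, 1 gave as many such probes, the real one, with 4277 against 2989 for the highest other. For gene lists, 2 of the 8 turns gave as many, the real one with 2 and the highest other also with 2. Turning swap pair 3 alone, pairs 2 and 3, or pairs 3 and 4 gave 1 list each. With 8 turns no share under 0.05 can be reached.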

How the results depend on the processing

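The count of probes past the threshold, 0, depended on the unit of replication and on the filter. It was 941 without the replicate block (8 single arrays with a dye intercept), 404 without that intercept, 674 with slide set as a block and 194 with slide as a random block. All 4 fits enter the 2 arrays of a swap pair separately. Only the first was simulated, with variances taken from the pairing used, and there 107.2 of 285.4 calls were false. Over the 24 pairings the count was 0 to 2010, with a median of 619, and the pairing used and 1 other gave 0. The rule joins arrays that deviate alike, which enlarges the spread between averaged pairs and so tends to lower the count. The pairing used also gave the fewest probes at an unadjusted p under 0.05 (limma), 4277 against 4779 to 7228 for the others. The strict filter gave 29 probes and the filter at 2 times the negative controls, chosen after seeing the data, gave 83, which include all 29; both test fewer probes. An unadjusted p under 0.05 with a fold of at least 1.5 gave 310. Leaving out each swap pair gave 0 each time.

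The number of lists, 2, was 8 with median centring (the same 2 and 6 lower in AAPH), 1 with the strict filter and 1 within slides 78 and 79 (the fibroblast list both times), 0 with an estimated correlation and 1 with fry; the cause was not tested. The list that passed with fry was apoptosis regulators, while the fibroblast and interferon lists did not pass it (adjusted p = 0.213 and 0.487). Leaving out each swap pair gave 2 to 3. The fibroblast list passed in 21 of 23 alternatives (adjusted p 3.84e-08 to 0.803) and the interferon list in 19 of 23 (3.47e-10, from swap pairs 1 and 2 alone, to 0.803). Trophectoderm markers passed in 5 of 23. Over the 23 alternatives the fibroblast median was 0.255 to 1.61 and the interferon median 0.0848 to 0.667; both lists had fewer members under the strict filter (5 and 7, medians 1.61 and 0.336) and at 2 times the negative controls (6 and 9, medians 1.2 and 0.667). SOD1, canx and CASP9 each passed in the most favourable of the 24 pairings and changed sign in 1 other alternative, SOD1 to -0.24 within slide 26. The Y-linked mean lay between -0.06 and 0.04 in 18 alternatives, and no Y-linked gene was left under either stricter filter.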

Other observations

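Several genes outside the fixed rule had high ratios in AAPH, and all were chosen after their values were seen. GEM, a small GTPase, had a log2 ratio of 2.45 ± 1.84 (SD, n = 4), STRA6, a retinol transporter, 2.41 ± 1.59, OLR1, a receptor for oxidized lipoprotein, 2.22 ± 1.66 and IFITM2 1.94 ± 1.74. NDP was at 1.89 ± 0.91, IGFBP7 at 1.88 ± 1.02 and the receptor kinase AXL at 1.78 ± 1.27. None passed after adjustment over all probes (limma), but NDP was among the 29 probes that passed under the strict filter (adjusted p = 0.0459), and NDP and IGFBP7 passed at 2 times the negative controls (adjusted p = 0.0341 and 0.0401). NDP met the strict filter only in AAPH RNA, with 7 arrays above background in control RNA. OLR1 was above background on 5 of 8 arrays in control RNA and AXL on 6, and swap pair 2 had the highest ratio for each of these 7. Without it GEM was at 1.57, STRA6 at 1.70, OLR1 at 1.4, IFITM2 at 1.15, NDP at 1.45, IGFBP7 at 1.39 and AXL at 1.18. STRA6 had 1 other kept probe, at -0.07, whereas the 2 other NDP probes had a median of 1.16.

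Of the genes that passed under the strict filter, 6 others were chosen after their values were seen. C1QTNF3 had a log2 ratio of 1.73 ± 0.75 (SD, n = 4), CTHRC1, a secreted collagen triple helix protein, 1.11 ± 0.43 and NCOA7 1.05 ± 0.45, each higher in 4 of 4 swap pairs. The 2 other C1QTNF3 probes had a median of 0.09 and a range of -0.04 to 0.22. Among the lower genes were PLCH1 at -1.17 ± 0.48, ARPP21 at -1.11 ± 0.39 and SHMT1, an enzyme of folate metabolism, at -0.93 ± 0.35. PLCH1 and ARPP21 signal ran over the AAPH pools in the same order as that of the 12 lower genes named by the rule. Control signal of ARPP21 ran in that order too, and that of PLCH1 was also highest in swap pair 1 and lowest in pair 3. The other ARPP21 probe was at 0.06.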
